A study of Bacillus amyloliquefaciens with 2 samples.

How the data were processed

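Transcript levels were measured by strand-specific RNA sequencing of Bacillus amyloliquefaciens strain BS-1, a soil bacterium used against plant disease. Per the labels and the design text, cells were grown in medium holding 75% (v/v) of a cell-free culture filtrate, from an inoculum of 2%, at 30 °C and 150 rpm for 24 h. The filtrate came either from a culture of the bacterium alone (BCF) or from a mixed culture with Trichoderma longibrachiatum, a filamentous fungus (MCF). Libraries were prepared from 3 µg of total RNA with a directional kit, per the labels' protocols. Each group holds 1 sample, so the 2 groups have no replicates.

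The submitters' processing notes name Bowtie2 2.2.3 and HTSeq 0.6.1, with no role or order. The genome build, the annotation and any filter are not given in the sources used here. The values deposited by the authors are in FPKM, reads or fragments of a locus scaled to its length and to the library total. No label or header states this unit. It was inferred from the deposited values, which sum to different totals in the libraries and step by an amount that differs between loci. RPKM and FPKM cannot be told apart this way. The table holds 1 column per sample and 3930 loci. The files give locus tags and do not pair them with gene names, and no reference genome was used here. The 41 gene lists fixed in advance therefore matched 0 loci, so no list and no gene is named, and the planned list medians were not computed. Coordinates and annotations were likewise not analysed here.

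Read numbers were recovered from the FPKM values. FPKM equals the reads of a locus divided by its length and by the library total. Ratios of low values between the libraries were small whole-number fractions times 1 constant, and 1087 such loci gave a ratio of library totals of 1.29. Totals of 5389668 (BCF) and 6973186 (MCF) were the largest at which most loci kept a whole length that is a multiple of 3. At these totals each of the 3798 loci with a value above 0 had a length between 30 and 20000 nt that made both values whole reads, within 1e-05 reads plus 5e-09 per read. With both totals raised by 0.371% as a control, 2.99% of the 3742 loci above 0 in both libraries had such a length. A first control, with the MCF values shuffled among loci, gave a length that is a multiple of 3 for 30.8% of these loci, and any whole length for 32.6%. It gave 30.6% at a first, wider tolerance of 0.001 reads. A shuffled pair has a solution wherever a common multiple of both lengths lies in the range tried, so a fit of single loci is weaker evidence than the fit of all of them. The raised totals were added as a control after the shuffled result was seen. The smallest such length was used for reads. It was a multiple of 3 for 90.0% of loci. The totals were chosen by this property, so this share is no independent support for the recovery. Reads found this way can be too small by a whole factor, and they add up to 87.9% (BCF) and 88.3% (MCF) of the totals. Coding lengths in the text are the smallest that are multiples of 3. Which loci are coding was not examined. These lengths are lower bounds only where the true length is a multiple of 3, and can be too long for other loci. On data simulated from these libraries, 78.2% of 3783 loci returned the true reads, and 99.5% the true reads or those divided by a whole number. The simulated lengths were the recovered multiples of 3. Loci of other lengths, or with a wrongly recovered length, were therefore not covered by this simulation.

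The design fixed before the data were examined assumed counts first and gave a second form for normalized values, which was used because the deposited values are FPKM. The comparison was the log2 ratio of FPKM + 1 in MCF over FPKM + 1 in BCF, on the values as deposited. This scale understates the change of low loci. A locus entered with at least 5 FPKM in at least 1 library. Loci with an absolute log2 ratio of at least 1 were counted. With 1 library per group no test was made and no p-value is given, and no difference has a replicate check. Intervals of ratios are exact (Clopper-Pearson) 95% intervals and intervals of shares are Wilson 95% intervals, both from the recovered reads. They cover counting error only, since each group has 1 library. The reads carry no molecular identifiers, so copies of 1 molecule count as separate reads and the intervals may be too narrow. In the simulated comparison, 200 loci were changed. The 2-fold limit found 92.0% of 25 loci raised 2.5-fold, 91.7% of 24 loci lowered 2.5-fold, and 100% of those changed 4-fold.

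The rule fixed before the data were examined named 10 loci per direction among those with a gene symbol. As 0 loci had one, the 2 highest and the 2 lowest log2 ratios of FPKM + 1 among entering loci are named by tag. The pseudocount keeps loci with few reads from leading this ranking. The following were chosen after the values were seen: the read recovery, the ranking by abundance, the blocks of neighbouring loci, the length classes and the groups of long loci. A block is a run of at least 3 entering loci with consecutive tags, 5 apart, all past the 2-fold limit in the same direction. Tag order was taken as a stand-in for gene order. Long loci are those of 5000 nt or more, grouped where their tags lie within 50 of each other. Random sets for the long loci were matched in 20 bins of mean expression. Bootstrap intervals resampled loci 1000 times, and describe the spread over loci, not over cultures. Alternatives changed the scaling of the libraries, the filter, the pseudocount and the lengths. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.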

Results

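To ask how a mixed culture of Bacillus amyloliquefaciens and Trichoderma longibrachiatum affects the bacterium, its transcript levels were measured in cells given filtrate of the mixed culture (MCF) and in cells given filtrate of the bacterium alone (BCF). Each group was represented by 1 library. Recovered library totals were 5389668 reads (BCF) and 6973186 reads (MCF), and the median entering locus had at least 203 and 210 reads, respectively. Of 3930 annotated loci, 3761 had a value above 0 in BCF and 3779 in MCF, and 132 were listed at 0 in both. A further 37 loci were listed at 0 in BCF alone, of which 34 had at most 3 recovered reads in MCF at their smallest length. Another 19 were listed at 0 in MCF alone, of which 17 had at most 3 recovered reads in BCF at their smallest length. These read numbers can be too small by a whole factor. For the loci with at most 3 recovered reads, whether a difference between the libraries was detectable at this depth therefore stays open. The most recovered reads were 17 in MCF among loci at 0 in BCF alone, and 5 in BCF among loci at 0 in MCF alone. At each of these read numbers, against 0, the counting interval of the ratio excluded 1. The table lists loci by tag without gene names, so loci are described by level, length and neighbourhood.

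The 2 transcriptomes were similar in rank order and differed in a limited set of loci. Across the 3371 loci that entered, Pearson's r of log2(FPKM + 1) was 0.97 and Spearman's rho was 0.96. These are correlations across loci, which are not independent replicates. In MCF, 73 loci (2.17%) were at least 2-fold higher and 239 loci (7.09%) at least 2-fold lower, while 3059 differed by less. At least 4-fold differences were seen in 14 higher and 37 lower loci. The higher loci had a median of 9.20 FPKM in BCF and 35.6 FPKM in MCF. The lower loci had a median of 54.9 FPKM in BCF and 17.6 FPKM in MCF. Each set was chosen by its ratio, and a locus could enter through 1 library alone. A low level in the other library therefore follows in part from the selection. Of the 312 differing loci, 283 had a counting interval of the ratio that excluded 1, of which 60 were higher and 223 lower.

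**Figure D1:**
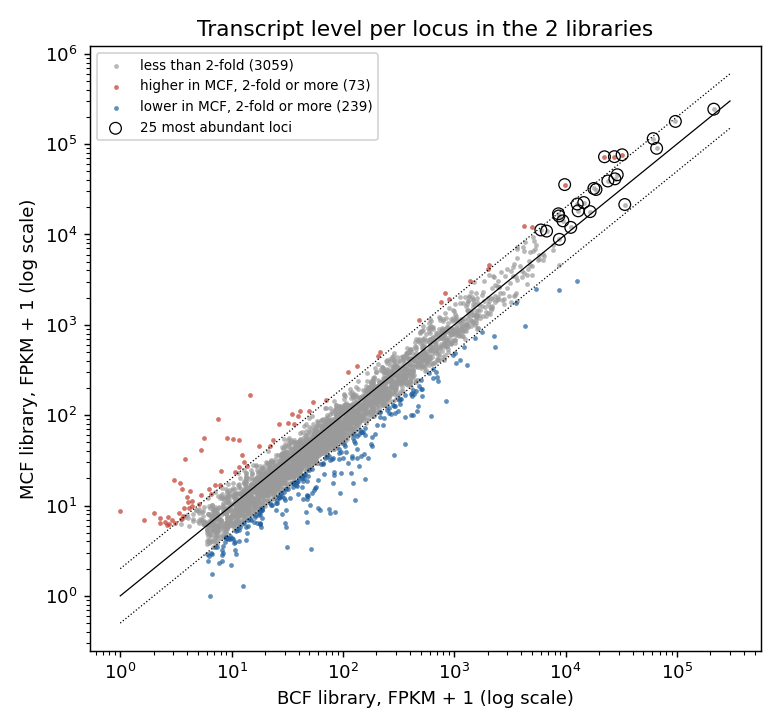
Each point is a locus that entered, with its FPKM + 1 in the BCF library (x, log scale) and in the MCF library (y, log scale). Dotted lines mark 2-fold, red points are the 73 higher loci, blue points the 239 lower loci, and circles the 25 most abundant loci, 24 of which had a higher value in MCF.

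The excess of lower loci depended on how the libraries were scaled. The median log2 ratio of all entering loci was -0.28, a level of 0.826 times that in BCF, and 70.5% of loci lay below 0. When MCF was rescaled so that the median ratio was 1, 143 loci were higher and 125 lower. When the summed FPKM of both libraries was equalised instead, 41 loci were higher and 558 lower, and 86.1% lay below 0. The share of higher loci among those differing was 23.4% as deposited and 53.4% with the median ratio set to 1.

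Many of the strongest differences lay in runs of neighbouring loci. Loci were ranked on the log2(FPKM + 1) scale, and on plain FPKM some loci with fewer reads had more extreme ratios. The highest on the ranking scale was AAV34_RS02990, at 88.6 FPKM in MCF and 6.50 FPKM in BCF, from 406 and 23 reads. Its plain FPKM ratio was 13.6 (95% counting interval 8.97 to 21.8), or 3.58 on the log2(FPKM + 1) scale. AAV34_RS03015 came next, at 164 against 13.7 FPKM, a ratio of 11.9 (8.86 to 16.5). Both lie in the same block of 8 consecutive loci, all higher in MCF, with log2 ratios of 2.41 to 3.58 and a median of 3.03. The median level in that block was 54.0 FPKM in MCF and 5.57 FPKM in BCF. The lowest on the ranking scale was AAV34_RS03490, at 2.28 FPKM in MCF and 50.2 FPKM in BCF. Its plain FPKM was 22.0-fold lower in MCF. The counting interval was 9.76 to 61.3 on the 6 MCF reads of its smallest length, 377 nt, and 13.7 to 37.6 on the 18 reads of a coding length of 1131 nt. It lies in a block of 9 loci, the largest seen, whose log2 ratios ran from -3.96 to -2.20 with a median of -3.03. AAV34_RS12020 was the second lowest on the ranking scale, at 10.6 against 127 FPKM, 11.9-fold lower (9.84 to 14.6), and lay in no block.

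In all, 20 blocks held 95 loci, 30.4% of those that differed by at least 2-fold. There were 3 higher blocks with 16 loci and 17 lower blocks with 79 loci. The other 2 higher blocks held 5 loci with a median log2 ratio of 1.52 and 3 loci with a median of 1.58. The first of these was weakly transcribed, at a median of 7.20 FPKM in MCF and 1.27 FPKM in BCF. Among the lower blocks, 1 of 7 loci had a median log2 ratio of -2.79 and included a locus of 7128 nt at 289 FPKM in BCF and 34.8 FPKM in MCF. A block of 5 loci had a median of -2.42 and a block of 8 loci a median of -2.04. More abundant was a block of 7 loci at a median of 474 FPKM in BCF and 126 FPKM in MCF, with a median log2 ratio of -1.90. With the median ratio set to 1, every locus stayed past 2-fold in 9 of the 20 blocks, and blocks called anew numbered 4 higher and 7 lower. With summed FPKM equalised they numbered 2 higher and 43 lower.

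**Figure D2:**
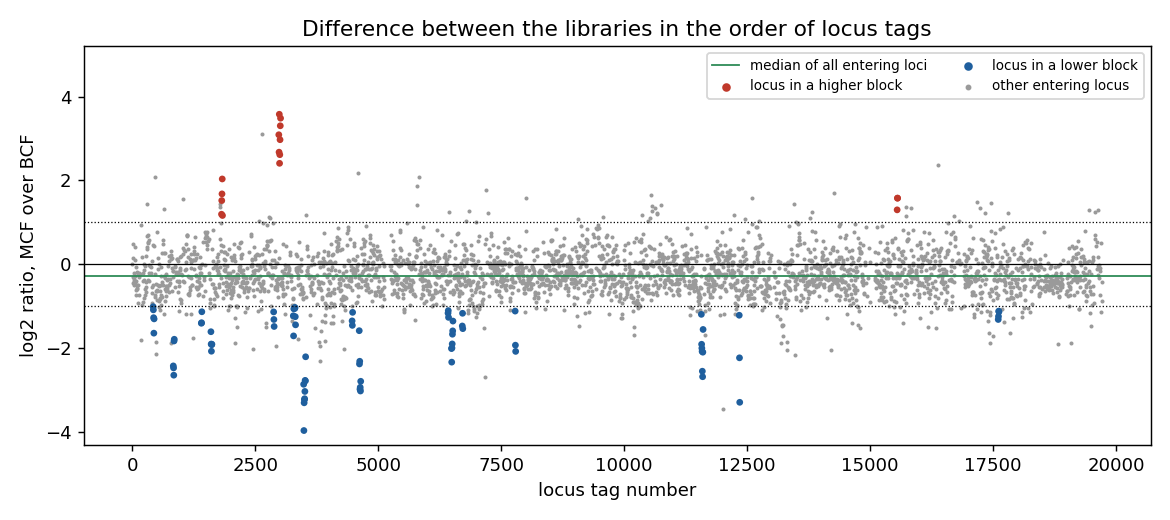
The log2 ratio of MCF over BCF (y) is plotted for each entering locus against its locus tag number (x). Red and blue points are the 95 loci in blocks, grey points the other loci, and the green line the median of -0.28.

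**Figure D3:**
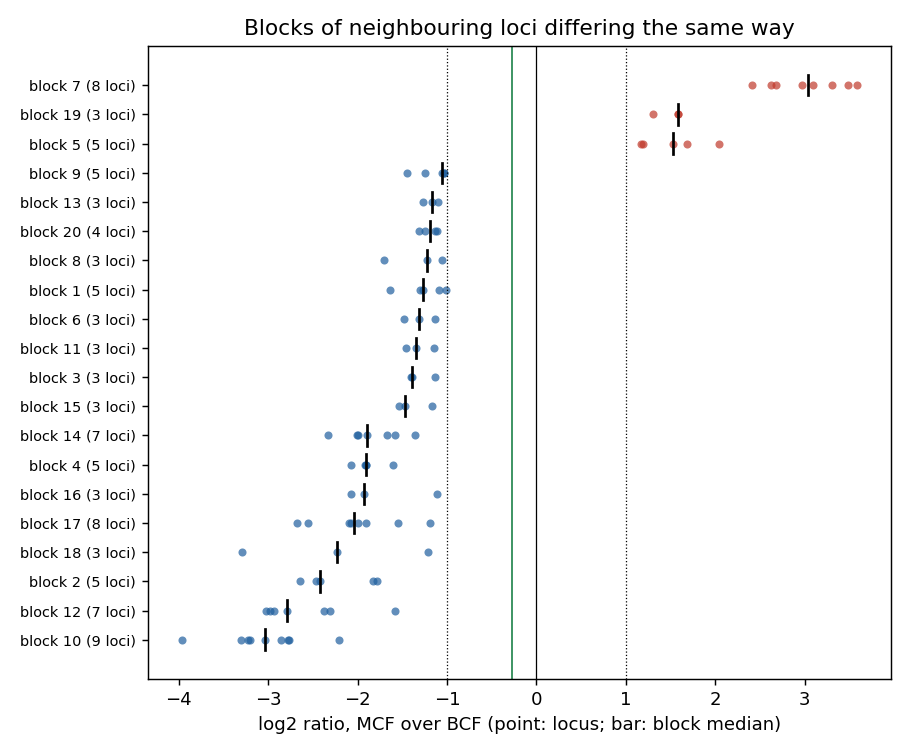
Each row is 1 of the 20 blocks, numbered in tag order, with a point per locus at its log2 ratio of MCF over BCF (x) and a bar at the block's median. Medians run from -3.03 in the block of 9 loci to 3.03 in the block of 8 loci; the green line is the median of all entering loci and dotted lines mark 2-fold.

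The 25 most abundant loci were mostly higher in MCF, and wider sets less so. Of the 25 loci with the highest mean FPKM, 24 had a higher value in MCF, with a median log2 ratio of 0.70, and 4 were at least 2-fold higher. Under the other scalings 20 to 24 had a higher value and 3 to 12 were at least 2-fold higher. Of the 50 most abundant loci, 39 had a higher value (33 to 46 under the other scalings), with a median log2 ratio of 0.61. Of the 100 most abundant, 61 had a higher value (45 to 79 under the other scalings), with a median of 0.22. Together the 25 loci took 25.4% of BCF reads (Wilson interval 25.3 to 25.4) and 37.2% of MCF reads (37.2 to 37.3), at the smallest lengths. With lengths in multiples of 3 the shares were 30.4% and 44.1%. These lie outside the intervals, which cover counting error and not the uncertainty of the recovered lengths. The most abundant locus of all had a recovered length of 363 nt, and whether it codes for protein was not examined. It stood at 214452 FPKM in BCF and 243711 FPKM in MCF, 1.14-fold on the log2(FPKM + 1) scale. The exception among the 25 was a locus of 285 nt, at 34021 FPKM in BCF and 21453 FPKM in MCF. Most of these loci were short, 15 of the 25 being under 300 nt.

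Among all 255 loci at 1000 FPKM or more in 1 library, 13 were at least 2-fold higher and 14 at least 2-fold lower, and the median log2 ratio was -0.06. The higher ones had a median coding length of 192 nt and the lower ones of 675 nt. The counts were 36 and 8 with the median ratio set to 1, and 5 and 25 with summed FPKM equalised, so which direction prevailed depended on the scaling. The 3 with the highest ratios were 228, 219 and 216 nt long. They stood at 35650, 72411 and 12532 FPKM in MCF against 9815, 22367 and 4189 FPKM in BCF, ratios of 3.63 (3.56 to 3.70), 3.24 (3.19 to 3.28) and 2.99 (2.90 to 3.09). The 2 lowest were 1116 and 1149 nt long. The first had 978 FPKM in MCF and 4324 FPKM in BCF and was 4.42-fold lower (4.31 to 4.54). The second had 3070 and 12733 FPKM and was 4.15-fold lower (4.09 to 4.21).

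Very long loci differed by neighbourhood. There were 31 loci with a coding length of 5000 nt or more, of which 25 fell into 6 groups and 6 stood alone. None was 2-fold higher in MCF under any of the scalings tried. As deposited 4 were 2-fold lower, against 1 with the median ratio set to 1 and 6 with summed FPKM equalised, and the median log2 ratio of the 31 loci was -0.27. That median lay at percentile 51.9 of 10000 random sets matched on mean expression. A pair of neighbours of 10755 and 10761 nt was lower in MCF, at 119 and 147 FPKM against 261 and 319 FPKM, with log2 ratios of -1.13 and -1.12. A group of 3 loci, the longest of 16086 nt, had a median of -0.91, and another group of 3 a median of -0.60. The largest group, 7 loci of 5727 to 15615 nt at 341 to 641 FPKM in BCF, had a median of -0.27, which became 0.014 when the median ratio was set to 1. A group of 5 loci, including the longest in the table at 16299 nt, was slightly higher, with a median of 0.15, which turned to -0.15 when summed FPKM was equalised. A last group of 5 weakly transcribed loci, at 5.37 to 20.8 FPKM in BCF, had a median of 0.00, which was 0.25 with the median ratio set to 1 and -0.27 with summed FPKM equalised. Within a group the log2 ratios spanned at most 0.40, whereas the medians of the groups spanned 1.28.

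Short loci had higher ratios than longer ones. The 643 entering loci under 300 nt had a median log2 ratio of -0.02, and the 2728 others one of -0.32. Recovered lengths can be too small by a whole factor, so the class under 300 nt may include longer loci. Loci from 300 to under 600 nt had a median of -0.24, those from 600 to under 1200 nt one of -0.34, and those from 1200 to under 3000 nt one of -0.39. The 24 loci from 3000 to under 5000 nt had a median of -0.48. The 31 loci of 5000 nt or more had one of -0.27, with a bootstrap interval over loci of -0.53 to -0.04. This interval includes -0.39 and -0.48, so whether the fall with length continued there cannot be told. Of loci under 300 nt, 4.51% were at least 2-fold higher and 5.29% at least 2-fold lower. Of those from 1200 to under 3000 nt, 1.27% were higher and 8.25% lower. Spearman's rho of length and log2 ratio across loci was -0.23.

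**Figure D4:**
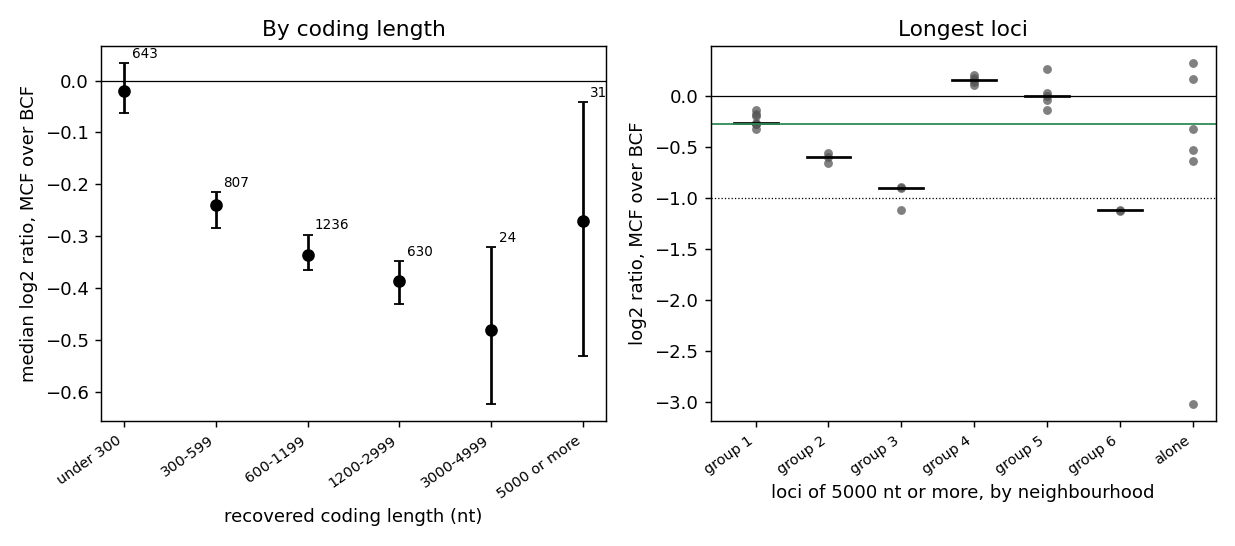
Left, the median log2 ratio of MCF over BCF (y) by recovered coding length in nt (x), with bootstrap 95% intervals over loci and the number of loci at each point. Medians go from -0.02 under 300 nt to -0.39 from 1200 to under 3000 nt and -0.48 from 3000 to under 5000 nt, and back to -0.27 at 5000 nt or more. Right, log2 ratios of the 31 loci of 5000 nt or more (points) by neighbourhood, with bars at the medians of the 6 groups and the median of all entering loci in green.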

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

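All settings for the counts per direction, the median, blocks, length classes, long-locus groups and read shares, and equal summed FPKM for any result, were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Leaving out a library was likewise not possible, and the planned medians of fixed gene lists, with their alternatives, were not run because no locus was paired with a gene name. Of 145 alternative values, 88 stayed within the limits set (1.5 times for a count, a counting or bootstrap interval for other values) and no value with an absolute log2 ratio of at least 1 changed sign. With the median ratio set to 1, 143 loci were higher, 125 lower, the median was 0 and 7 blocks were lower; with a trimmed mean of log ratios these were 137, 131, -0.020 and 8. With summed FPKM equalised, 599 loci differed (41 higher, 558 lower), the median was -0.58 and 43 blocks were lower. With the summed FPKM of all but the 10 most abundant loci equalised, which changes the scaling and the loci it rests on together, the median was -0.33. A filter of 50 FPKM left 157 differing loci (33 higher, 124 lower), r = 0.95 and a short minus long difference of 0.37, which was 0.42 at 100 FPKM. Without a filter r was 0.97 and the median was -0.25. A pseudocount of 5 gave 199 differing loci (46 higher, 153 lower) and a median of -0.24. Blocks of at least 4 loci numbered 9 lower. With lengths in multiples of 3, the 25 most abundant loci took 30.4% of BCF and 44.1% of MCF reads. The medians of the 6 groups of long loci, in tag order, were 0.014, -0.33, -0.62, 0.44, 0.25 and -0.84 with the median ratio set to 1, and -0.0083, -0.35, -0.65, 0.41, 0.23 and -0.86 with a trimmed mean. With summed FPKM equalised they were -0.58, -0.90, -1.22, -0.15, -0.27 and -1.43, so the signs of 3 groups depended on the scaling. With the summed FPKM of all but the 10 most abundant loci equalised, groups 1, 3, 4 and 6 were at -0.32, -0.96, 0.10 and -1.18, and a pseudocount of 5 moved the second to -0.51. A scaling multiplies every MCF value by 1 factor, which by itself shifts all ratios in the same direction. On the log2(FPKM + 1) scale, loci at a low level in MCF shift less. For the other settings the cause was not tested. Depth may limit loci near the filter, since 76 entering loci had fewer than 10 recovered reads in both libraries. Recovered reads can be too small by a whole factor.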

Other observations

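Neighbouring loci varied together. Pearson's r of the log2 ratios across pairs of loci was 0.45 for direct neighbours (3078 pairs), 0.28 at a distance of 2 loci and 0.12 at a distance of 5 loci. At 20 loci it was 0.00, within the range of shuffled ratios (-0.06 to 0.05). With all loci of the blocks left out, r was 0.28 for direct neighbours (2968 pairs), 0.10 at 2 loci and 0.068 at 5 loci, each above the highest of 200 shuffles, while at 10 loci (0.048) it lay within their range. These are correlations across loci, not across samples. The level of a block in BCF ranged from weak (median 1.27 FPKM in a higher block of 5 loci) to strong (median 648 FPKM in a lower block of 3 loci, at 254 FPKM in MCF). With the median ratio set to 1, all 5 loci of the weak block stayed past 2-fold, and 2 of the 3 loci of the strong block.

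All tests below were chosen after the results were seen, except the simulation of counting noise, which was planned before its outcome was known. A planned simulation of depth was dropped, because values scaled to their own library totals give a median near 0 at any depths, and a test on deeply read loci took its place. The test of abundant short loci was first set for each of 5 abundance classes, where it decided nothing because the interval in 1 class reached below 0, and was then reset to the 4 lower classes as 1 set. In 100 simulations at these depths with no locus changed, at most 51 loci passed 2-fold, against 312 observed, and no simulation gave a block. This argues against counting noise as the whole source of the differing loci. Differences between cultures of the same treatment were not measured, so how many of the 312 would recur in other cultures is open.

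The first pattern is that most loci lie below 0. A difference in depth would act through loci with few reads. The median of the 2235 loci with a mean of at least 100 reads was -0.28 (bootstrap 95% interval -0.31 to -0.26). That of the 1136 loci with fewer reads was -0.25. The 2235 loci are most of those behind the overall median, so their median is not independent of it. The fall was not confined to loci with few reads, which argues against depth as its source. A candidate explanation is that a few loci took more of the reads in MCF, which lowers all others in a measure scaled to the library total. The higher read share of the 25 most abundant loci goes by arithmetic with a shift of -0.25 in the rest (-0.32 with lengths in multiples of 3, and -0.18 for the 10 most abundant loci). This restates the fall of the rest and is no independent test of it. Whether the abundant transcripts increased, the rest decreased or library preparation differed stays open with 1 library per group.

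The second pattern is the blocks. Ratios placed at random among loci gave at most 5 blocks in 1000 shuffles (median 1), against 20 observed. Reads assigned across the boundary of direct neighbours would not link loci 3 tags apart, whose r was 0.22, above the highest of 200 shuffles (0.044). Shared transcription of neighbouring genes, as in bacterial operons, may underlie the blocks; this is a hypothesis, since the tags were taken as gene order and no annotation was used. A response to the filtrate and a chance difference between 2 cultures stay open for each block.

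The third pattern is the link with length. Against a few abundant short loci as its source, the median of loci under 300 nt minus that of longer ones was 0.25 (bootstrap 95% interval 0.18 to 0.31) over the 4 lower of 5 abundance classes together. By class, from the least abundant, it was 0.19, 0.22, 0.27, 0.32 and 0.44, and the interval in the second class included 0 (-0.013 to 0.32). A length bias that differs between the libraries and a real change of short transcripts cannot be told apart with 1 library per group. For loci of 5000 nt or more, coding length alone is argued against, because the group medians spanned 1.28 and the widest single group 0.40. In Bacillus, coding sequences of this length are mostly those of nonribosomal peptide and polyketide synthases, which make antibiotics; that these loci are such genes was not tested.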
